A study of Mus musculus with 27 samples.

How the data were processed

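The series measured messenger RNA by sequencing in 27 libraries from mouse thyroid. Per the labels, 24 libraries came from 12 tumor cell lines that carry the mutant Braf allele, and 3 libraries are marked wildtype and untreated. The lines fall into 4 genotypes with 3 lines each: Braf alone, or Braf with a knockout (KO) of Arid1a, Arid2 or Smarcb1, which encode subunits of the SWI/SNF chromatin remodeling complex. Each line has a library treated with vehicle and a library treated with CH5126766 (CKI), an inhibitor of RAF and MEK, at 300 nM for 8 days. The labels mention bovine TSH in wording that leaves open whether the vehicle arm received it. RNA was extracted with TRIzol and libraries were made with a TruSeq kit, per the labels. Per the submitters' processing notes, the mm9 build, STAR 2.4, HTSeq 0.6.1 and DESeq2 were used, and the notes do not say which step each tool did. Gene annotation, strand setting and filters are not given in the sources used here.

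The deposited values are raw counts per gene symbol for 33924 symbols, made by the authors with 1 column per library, and all columns were mapped to a sample. Symbols were used as deposited, and no coordinates were assigned. Total counts ranged from 18417255 to 27257703 per library, except for the CKI libraries of Smarcb1 KO lines BS53958 (11684983) and BS53965 (2884130). A gene with a count of 0 was treated as having at most 3 counts over its group, and a fold against such a group is given as a lower bound. These bounds cover counting error only.

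Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered with filterByExpr by group, libraries were scaled by the trimmed mean of M values (TMM), and 1 mean per group was fitted with the quasi-likelihood F test. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The 24 tumor line libraries shared 1 fit with 15634 genes. The libraries marked wildtype entered only the comparison of Braf vehicle with wildtype, in a fit of all 27 libraries with 16821 genes. The 15 comparisons were each KO against Braf in vehicle, CKI against vehicle in each genotype, the difference between the CKI response of each KO (and the mean of the 3 KO) and that of Braf, each KO against Braf under CKI, and Braf vehicle against wildtype. Levels are CPM, the counts of a gene relative to the TMM-scaled size of its library. Standard errors of log2 changes were derived from the F statistic and are approximate.

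The groups, comparisons, tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. The alternatives were size factors of the RLE type, DESeq2 1.42.0 with its own filter, no filter on low counts, a filter of at least 1 CPM in at least 6 libraries, only the compared groups in the fit, all 27 libraries in the fit, each line or library left out in turn, and, for comparisons with CKI against vehicle, the cell line as a replicate block, which left 8 residual degrees of freedom. The pairing of vehicle and CKI libraries by line was checked from the counts. After the mean of each group was removed, the correlation across genes of the paired libraries lay between 0.259 and 0.773 in all 12 lines, and that with the other lines of the genotype was negative. With 3 libraries per group, removing the mean makes other lines negative on balance where the own line is positive. The negative values thus add no separate evidence of the pairing. Added after the data were seen were fits without lines BS53958 and BS53965, fits with every library thinned at random to the depth of the shallowest, the rule for the largest changes applied to the blocked fit, and the blocked fit with lines left out or counts thinned.

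Of 27 gene lists with 393 entries, 384 entries were found in the table. The lists were thyroid differentiation, thyroid hormone handling and follicle genes, MAPK output, cell cycle, SWI/SNF subunits, epithelial, mesenchymal, AP-1, TGF-beta and YAP response, receptor tyrosine kinases and ligands, interferon response, MHC class I presentation, cholesterol synthesis, cilium, endoplasmic reticulum stress, glycolysis and hypoxia, acute stress and heat shock, sex-linked genes, and markers of fibroblasts, leukocytes, endothelium, C cells, parathyroid, adipocytes, skeletal muscle, red blood cells and respiratory or stratified epithelium. Lists with at least 3 measured members, 25 in all, were tested as sets with camera at a preset correlation of 0.01, adjusted over all lists and comparisons of the same kind, with an estimated correlation and fry as alternatives. The sex-linked genes served as a check of the pairing only. The text names the targeted genes, all members of the thyroid lists and the MAPK output list, up to 4 called members of every other list with the smallest adjusted p, and the largest rises and falls among called genes with an average log2 CPM of at least 2 and no overlap between the groups' libraries. Up to 8 such changes each way were named for the comparisons of KO with Braf in vehicle, CKI in Braf, the CKI response and wildtype, and up to 5 for the others. For 3 libraries against 3, groups of an unchanged gene do not overlap by chance in 10% of cases.

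The pipeline was tested on simulated data of the same depth, with 200 changed genes per comparison. For Arid1a KO against Braf in vehicle, edgeR recovered 46% of genes changed 4-fold and 11% of genes changed 2-fold, and 5% of its calls were false, against 26.1% of the calls of DESeq2. For CKI in Braf lines, 50% of genes changed 4-fold were recovered without the block and 69% with it. For the CKI response of Smarcb1 KO lines these shares were 25% and 41%. Libraries were drawn independently around the fitted means, and the simulations were not repeated. Without the block the simulated data thus lacked the correlation of paired libraries, so the false shares need not hold for the real calls. Transcript isoforms, sequence variants and the excised exons were not analysed here, and some named genes and their values are not reported here.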

Results

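RNA levels were measured in mouse thyroid tumor cell lines driven by a mutant Braf kinase, with or without loss of a SWI/SNF subunit, and in libraries marked wildtype. The 27 libraries formed 9 groups of 3. Each tumor line genotype (Braf alone, Arid1a KO, Arid2 KO and Smarcb1 KO) had 3 lines in vehicle and the same 3 lines under CKI. The wildtype libraries are marked untreated, and their source is still given as a tumor cell line. Total counts ranged from 18417255 to 21477216 in Braf vehicle, from 22916299 to 27257703 in Braf CKI and from 20860235 to 26670135 in Arid1a KO libraries. They ranged from 21529574 to 24065456 in Arid2 KO libraries, from 20043316 to 23469129 in Smarcb1 KO vehicle libraries and from 21729891 to 22138360 in wildtype libraries. The Smarcb1 KO CKI libraries held 22351748 counts in line BS53736, 11684983 in BS53958 and 2884130 in BS53965. Levels are mean CPM ± SD (SD, n = 3 lines), changes are log2 ± SE, and p-values are edgeR adjusted p-values. These p-values rest on the spread between separately derived lines, pooled over vehicle and CKI libraries. Without the block the 2 libraries of a line were counted as independent, though they were correlated (r from 0.259 to 0.773), so the spread was known from fewer lines than libraries.

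Of the targeted genes, Smarcb1 was nearly absent from its KO lines and Arid1a was lowered, while Arid2 was not. Smarcb1, a core subunit, was at 0.461 ± 0.612 CPM in Smarcb1 KO and 74.9 ± 9.06 CPM in Braf vehicle libraries (log2 change -7.34 ± 0.86, adjusted p = 7.72e-05). Under CKI it was at 1.6 ± 1.58 and 77.4 ± 14.3 CPM. Arid1a, a DNA-binding subunit, was at 80.5 ± 13.8 CPM in Arid1a KO and 132 ± 3.86 CPM in Braf vehicle libraries (-0.71 ± 0.17, adjusted p = 0.0325). Under CKI it was at 74.6 ± 12.4 against 127 ± 11.3 CPM, which did not pass (adjusted p = 0.0523). Arid2 was at 94 ± 14.3 CPM in Arid2 KO and 97.6 ± 10.2 CPM in Braf vehicle libraries (-0.05 ± 0.24, adjusted p = 0.968), and at 128 ± 40.7 against 118 ± 13.1 CPM under CKI, so counts over the whole gene do not check this label. Wildtype libraries held Arid1a at 131 ± 20.2, Arid2 at 81.4 ± 2.05, Smarcb1 at 81.3 ± 4.7 and Braf at 69.6 ± 15.2 CPM. Braf was at 49.1 ± 3.65 CPM in Braf vehicle and 79.7 ± 27.1 CPM in Braf CKI libraries.

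**Figure D1:**
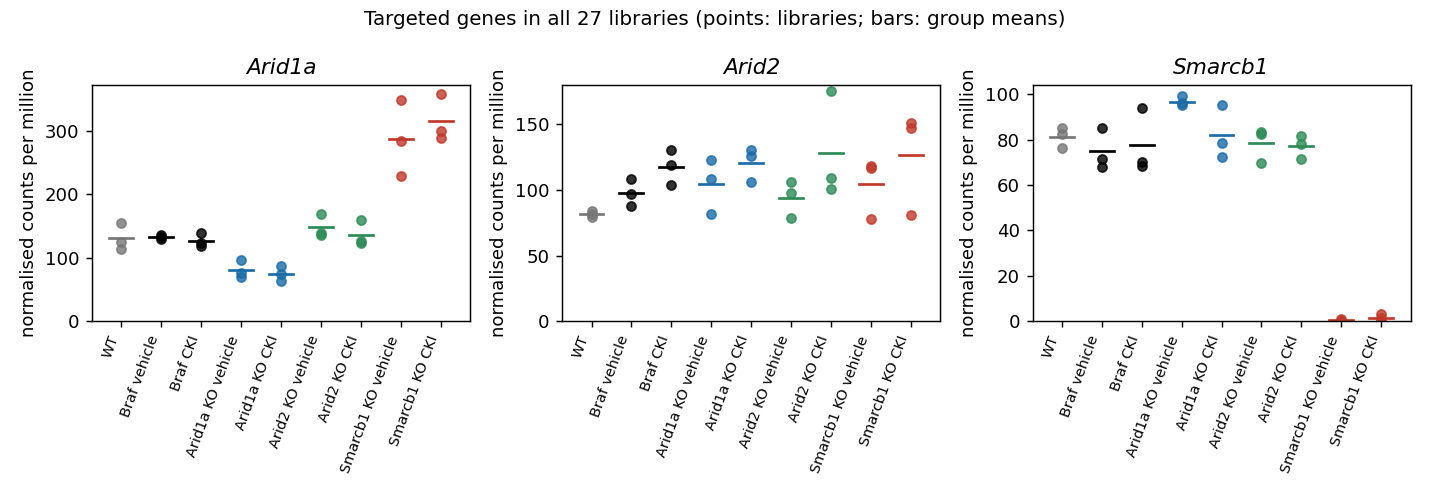
Normalised CPM of Arid1a, Arid2 and Smarcb1 in the 27 libraries by group, with points for libraries and bars for group means. Smarcb1 lies near 0 in the Smarcb1 KO libraries, Arid1a is lowered in Arid1a KO libraries, and Arid2 is not lowered in Arid2 KO libraries.

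The first comparison asked how Braf tumor lines differ from thyroid marked wildtype. Thyroid differentiation genes were lower for 10 of 15 measured members and higher for 0 (12 lower adjusted over the list alone). Thyroglobulin (Tg), the hormone precursor, was at 3.54 ± 3.36 CPM in Braf vehicle and 283000 ± 59300 CPM in wildtype libraries (-16.28 ± 2.27, adjusted p = 1.72e-05). The iodide transporter Slc5a5 (-9.16 ± 0.79, adjusted p = 1.54e-07) was lower, as were Duox2, Foxe1 and the TSH receptor Tshr (-8.8 ± 2.08, adjusted p = 0.00203). The deiodinase Dio1 was at least 13000-fold lower and, in the hormone handling list, Iyd was at least 17500-fold lower. The transcription factors Pax8 (-2.46 ± 1.09, adjusted p = 0.0697) and Nkx2-1 (-1.86 ± 0.8, adjusted p = 0.0626) did not pass. The thyroid differentiation list moved down as a set (camera adjusted p = 2.97e-08, and adjusted p = 0.000519 with an estimated correlation). In the hormone handling list 7 members were lower, including Slc26a7 (-11.64) and Lrp2 (-6.9), and 4 were higher, namely Ano1, Clcn5, Kcnq1 and Slco4a1. MAPK output genes, transcribed on ERK signaling, were higher for 15 of 19 members (16 adjusted over the list alone; set test adjusted p = 8.5e-10, and adjusted p = 0.00141 with an estimated correlation). Cyclin D1 (Ccnd1) was at 2660 ± 578 against 37 ± 2.63 CPM (6.17 ± 0.68, adjusted p = 1.73e-06), and Dusp4 (5.38 ± 0.75), Etv4 (6.79) and Spred3 (4.02 ± 0.26) were higher.

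**Figure D2:**
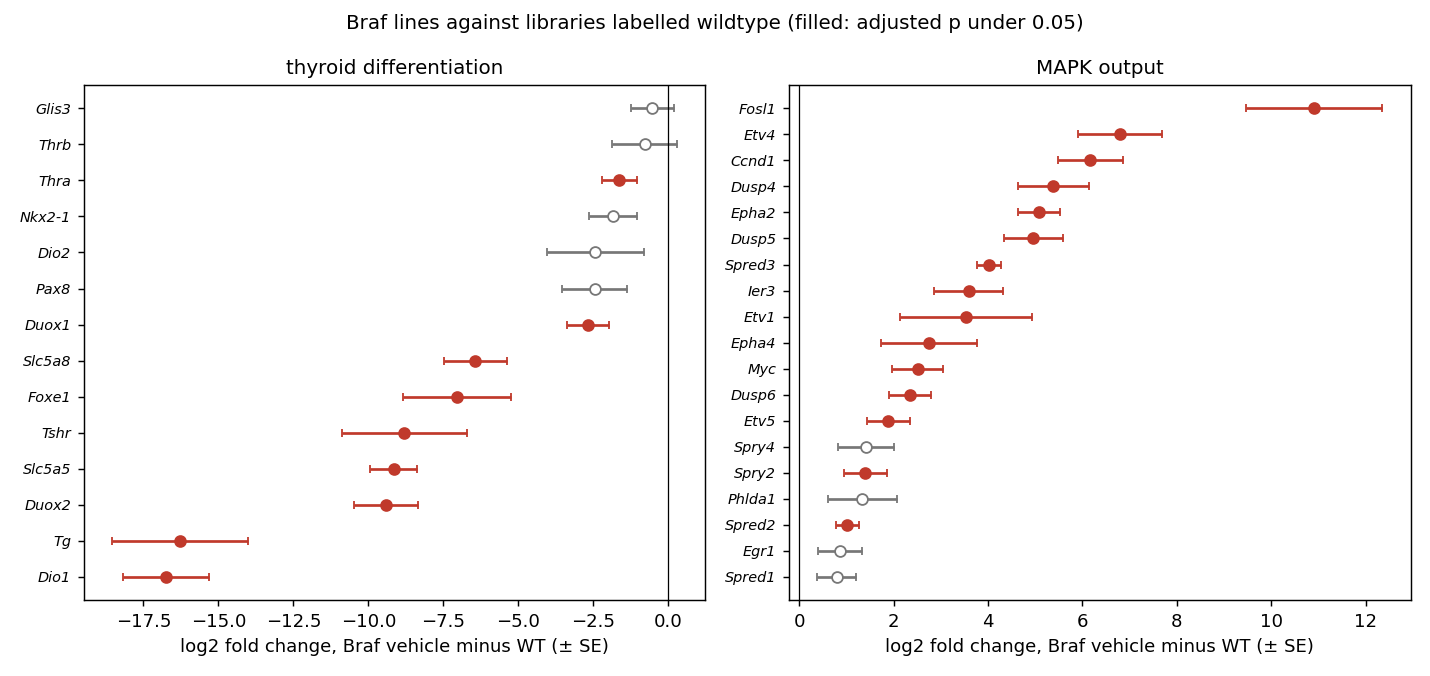
Log2 change ± SE of members of the thyroid differentiation and MAPK output lists in Braf vehicle against wildtype libraries (3 against 3), with filled points for adjusted p under 0.05. The thyroid genes plotted that pass are lower, and of the MAPK output genes 15 pass and all 15 are higher.

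Proliferation genes were higher in Braf lines and markers of tissue cell types were lower. All 28 cell cycle genes were higher, such as Cdk1 (6.13), Top2a (6.27) and Bub1 (7.16), with a set test adjusted p = 4.75e-24, and adjusted p = 0.0644 with an estimated correlation. Cholesterol synthesis genes were higher for 18 of 19 members, such as Cyp51 (3.43) (set test adjusted p = 1.27e-08, and adjusted p = 0.154 with an estimated correlation). TGF-beta and YAP response genes were higher for 7 of 16, including Ankrd1 (7.59) and Cyr61 (5.37) (set test adjusted p = 0.00176, and 0.0195 with an estimated correlation). Antigen presentation by MHC class I was lower for 9 of 12 genes, such as Tap2 (-4.17) and Psmb9 (-7.16) (set test adjusted p = 0.000356, and adjusted p = 0.215 with an estimated correlation), and interferon response genes were lower for 10 of 21 (0.0199, and adjusted p = 0.591 with an estimated correlation). Markers were lower for 9 of 9 leukocyte genes (Csf1r, -10.62), 10 of 10 endothelial genes (Pecam1, -9.99), 8 of 10 fibroblast genes (Dpt, -11.2), 7 of 8 adipocyte genes (Fabp4, -13.92), 8 of 8 skeletal muscle genes (Ckm, -13.49), 5 of 5 red blood cell genes and 6 of 7 C cell genes (Calca, -11.76). The parathyroid hormone gene Pth was at least 20400-fold lower, and Casr was lower (-7.48). Among epithelial genes 0 of 20 passed in either direction, with 7 of 20 members over 1 CPM in Braf line B52482 and 19 and 20 in the other Braf lines. In the remaining lists, 9 SWI/SNF subunit genes were higher and 4 lower, 3 mesenchymal genes were higher and 3 lower, and 6 AP-1 genes were higher and 2 lower. Receptor tyrosine kinases and ligands gave 7 higher and 5 lower, cilium genes 1 and 2, endoplasmic reticulum stress genes 1 and 7, glycolysis and hypoxia genes 6 and 4, acute stress genes 4 and 1, and respiratory or stratified epithelium markers 2 and 0.

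Over all genes, 7815 were called between Braf vehicle and wildtype, 3980 higher and 3835 lower. The largest rises were Prss22 (at least 946-fold), Serpinb9b (at least 695-fold), Csn3 (at least 349-fold), Gad2 (at least 176-fold), the mesothelin gene Msln (1200 ± 786 CPM, log2 change 10.96) and the ligands Wnt10a and Wnt7a. Beside thyroid and parathyroid genes, the largest falls were the muscle gene Myh4 (at least 9160-fold), Cfd (at least 8760-fold) and Hbb-b1 (at least 7660-fold). Cultured lines were here set against libraries that held markers of many tissue cell types, so the comparison does not isolate the Braf allele. With RLE size factors the median log2 change of all genes moved by -0.16, from 0.02 to -0.14, which is small beside the changes named, and no list changed from mostly higher to mostly lower members, while receptor genes were even, with 6 higher and 6 lower. With DESeq2 receptor genes gave 6 higher and 7 lower.

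The loss of Arid1a was compared with Braf alone in vehicle. Arid1a KO lines had less RNA of cholesterol synthesis and epithelial genes, and few thyroid or MAPK output genes passed. Cholesterol synthesis genes were lower for 9 of 19 members (15 adjusted over the list alone), such as Dhcr7 (-1.87 ± 0.4, adjusted p = 0.0191), Sc5d (22.6 ± 3.79 against 63.9 ± 21.9 CPM) and Nsdhl. The set test gave adjusted p = 4.36e-12, and adjusted p = 0.382 with an estimated correlation. Epithelial genes were lower for 6 of 20 (16 adjusted over the list alone; set test adjusted p = 4.8e-09, and adjusted p = 0.699 with an estimated correlation), such as the tight junction gene Marveld2 (-8.6 ± 1.98, adjusted p = 0.0258) and the protease gene St14 (0.206 ± 0.0937 against 204 ± 183 CPM). Braf line B52482 was low too, though above the Arid1a KO lines, with a median log2 CPM of 0.06 over the list against 5.99 and 7.32 in the other Braf lines and -0.22, -0.71 and -0.83 in Arid1a KO lines. Fibroblast matrix genes were higher for 2 of 10 (7 adjusted over the list alone), namely Dcn (468 ± 478 against 3.45 ± 3.42 CPM) and Col1a2 (set test adjusted p = 0.00037, and adjusted p = 0.311 with an estimated correlation). Of 12 thyroid differentiation genes only the hormone receptor Thrb was lower (0.584 ± 0.487 against 18.4 ± 22.2 CPM, -4.98 ± 1.36, adjusted p = 0.049), and Tg (0.85 ± 1.37, adjusted p = 0.804) did not pass. The chloride exchanger Clcn5 was lower among 12 hormone handling genes (-1.08 ± 0.29, adjusted p = 0.0458). Among MAPK output genes the ERK feedback inhibitor Spry4 was higher (203 ± 4.11 against 29.3 ± 29.1 CPM, adjusted p = 0.0251) and Epha4 was lower (2 ± 1.46 against 61.9 ± 18.1 CPM, adjusted p = 0.0313).

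Interferon response genes were higher as a set in Arid1a KO lines (adjusted p = 0.00164, and adjusted p = 0.699 with an estimated correlation), with 15 of 20 members passing when adjusted over the list alone and only Isg15 over all genes. Isg15 was at 157 CPM in line BA45198 and at 1.97 and 1.75 CPM in the other Arid1a KO lines. The glucose kinase Hk2 was lower (37.8 ± 6.76 against 212 ± 86.8 CPM, -2.49 ± 0.6, adjusted p = 0.0314), as were the ligand Tgfa (-4.79), the cilium factor Foxj1 (-7.13) and Foxa1 (-3.83). The mesenchymal list was higher as a set (adjusted p = 0.00291, and adjusted p = 0.699 with an estimated correlation) with 0 of 20 members passing. The largest rises were Slit3 (52 ± 37.6 CPM, 9.49 ± 1.53, adjusted p = 0.00516), Mgp, Adcy8, Cbln1, Ptgfr, the fibrillin gene Fbn2 (324 ± 121 against 0.937 ± 1.62 CPM), the retinoic acid binding gene Crabp1 (672 ± 233 against 2.2 ± 3.46 CPM) and Dlk1 (8.26). Among the largest falls were Cblc (at least 409-fold), Sh3rf2 (at least 213-fold), 4930506M07Rik, 1110050K14Rik (at least 131-fold), St14, Mpzl2 and the amino acid transporter Slc38a1 (-9.85 ± 1.61, adjusted p = 0.00439). In all, 567 genes were called, 153 higher and 414 lower, and 24 were called with only the 2 compared groups in the fit. The count was 107 without B47275, 118 without B48051, 181 without BA45198, 69 without BA47473 and 128 without BA49112, and rose to 1153 without B52482.

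**Figure D3:**
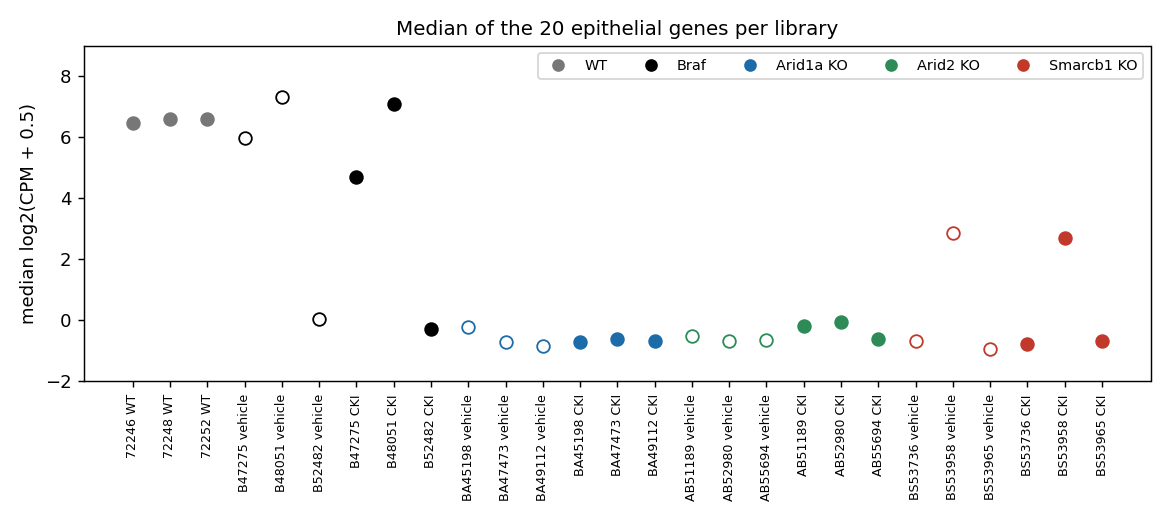
Median log2(CPM + 0.5) over the 20 epithelial genes in each library, by group. Braf vehicle libraries B47275 and B48051 lie at 5.99 and 7.32, B52482 at 0.06, and Smarcb1 KO vehicle library BS53958 at 2.87.

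The loss of Arid2 gave 8 called genes against Braf in vehicle, 1 higher and 7 lower, with 1940 genes at an unadjusted p under 0.05, 602 called by DESeq2 and 0 called with only the 2 compared groups in the fit. The calcium channel gene Cacna1a was higher (31.3 ± 8.56 against 3.98 ± 1.23 CPM, 2.98 ± 0.49), and Rasl11b (-4.05 ± 0.7), the paraoxonase Pon3 (3.87 ± 1.75 against 54.5 ± 28.1 CPM, -3.81 ± 0.67), Arap1, Scamp5 and Tapbpl (-1.15 ± 0.19) were lower, each at adjusted p = 0.0381. None of the thyroid or MAPK output genes passed, and Tg changed by 1.46 ± 1.38 (adjusted p = 0.745). Epithelial genes were lower as a set (adjusted p = 4.36e-12, and adjusted p = 0.576 with an estimated correlation), with 0 of 20 members passing over all genes and 13 when adjusted over the list alone. Braf line B52482, at a median of 0.06, was closer to the Arid2 KO lines, at -0.52, -0.68 and -0.65, than to B47275 and B48051, at 5.99 and 7.32. The TGF-beta and YAP response list (adjusted p = 0.00416, and adjusted p = 0.13 with an estimated correlation) and the cholesterol list (adjusted p = 0.0188, and adjusted p = 0.712 with an estimated correlation) were lower as sets with 0 members passing. Of 5 skeletal muscle genes 4 were higher adjusted over the list alone, from line AB52980. The count of calls was 0 without B47275, AB51189 or AB52980, 5 without B48051, 4 without AB55694 and 147 without B52482.

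The loss of Smarcb1 changed the most genes of the 3 knockouts, with 2837 called in vehicle (1083 higher, 1754 lower). The count was 785 with only the 2 compared groups in the fit and 837 without lines BS53958 and BS53965. Fibronectin (Fn1, 123 ± 207 against 12200 ± 6950 CPM, -6.61 ± 1.47), Mmp2 (-9.62), and the collagens Col6a3 (at least 118-fold), Col1a1 (-6.7) and Col3a1 (-5.37) were lower, while the mesenchymal and fibroblast lists did not move as sets (adjusted p = 0.713 and 0.195). TGF-beta and YAP response genes were lower for 5 of 16 members (9 adjusted over the list alone), with the receptor Tgfbr2 at 99.1 ± 26.5 against 734 ± 353 CPM (-2.89 ± 0.56, adjusted p = 0.00292) and Ctgf, Cyr61 and Tgfbr1 also lower (set test adjusted p = 0.0025, and adjusted p = 0.13 with an estimated correlation). Epithelial genes were lower for 5 of 20 (17 adjusted over the list alone; set test adjusted p = 0.000183, and adjusted p = 0.699 with an estimated correlation), such as the keratin Krt18 (25.7 ± 35.5 against 1470 ± 683 CPM) and Elf3 (-6.7), with Braf line B52482 low and Smarcb1 KO line BS53958 at an intermediate 2.87. MHC class I genes were higher for 4 of 12 (5 adjusted over the list alone), with the peptide transporter Tap2 at 24.5 ± 10.3 against 2.14 ± 0.571 CPM (3.51 ± 0.54, adjusted p = 0.000625) and the proteasome subunits Psmb8, Psmb9 and Psmb10 (set test adjusted p = 0.00623, and adjusted p = 0.699 with an estimated correlation). Of 25 SWI/SNF subunit genes 5 were higher and 19 did not pass (set test adjusted p = 0.186), and those higher included Arid1a (287 ± 59.4 CPM, 1.1 ± 0.18, adjusted p = 0.000737), the ATPase Smarca4 (0.77 ± 0.13, adjusted p = 0.00141) and Actl6a (0.85 ± 0.18).

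Thyroid and MAPK output genes moved in part in Smarcb1 KO lines in vehicle. Of 12 thyroid differentiation genes the factor Glis3 was lower (1.04 ± 0.94 against 38.6 ± 8.91 CPM, -5.22 ± 0.93, adjusted p = 0.00158), and Tg (-2.44 ± 1.51, adjusted p = 0.273) and Tshr (-1.06 ± 2.02) did not pass. Hormone handling genes were lower for 4 of 12 (7 adjusted over the list alone), namely Cdh16 (-8.49), Clcn5, Hhex (-3.63) and the potassium channel Kcnq1 (0.787 ± 1.13 against 79.8 ± 76.9 CPM), with a set test adjusted p = 0.00221, and adjusted p = 0.13 with an estimated correlation. Among 19 MAPK output genes, Spry4 (402 ± 158 against 29.3 ± 29.1 CPM, 3.77 ± 0.66, adjusted p = 0.00149), Dusp5, Epha2 and Spred2 were higher, and the ERK phosphatase Dusp4 (8.34 ± 6.26 against 210 ± 75.5 CPM, -4.65 ± 0.73, adjusted p = 0.000659) and Epha4 (-6.52 ± 1.29) were lower. Cell cycle genes were higher as a set (adjusted p = 0.000319, and adjusted p = 0.699 with an estimated correlation) with Pcna (1.08) and Ccne2 (1.64) passing, and 0 of 28 adjusted over the list alone. Cholesterol genes were lower for 4 of 19 (set test adjusted p = 0.0174, and adjusted p = 0.712 with an estimated correlation), such as Cyp51 (-1.48). Of 15 glycolysis and hypoxia genes 4 were lower, namely Hk2 (23.7 ± 8.37 against 212 ± 86.8 CPM), Ndrg1, Egln3 and Vegfa, and 1 was higher (set test adjusted p = 0.186). Of 14 endoplasmic reticulum stress genes Ddit3 (1.94 ± 0.42), Atf4 and Chac1 were higher, Dnajc3 was lower and 10 did not pass (set test adjusted p = 0.153). Hmox1 (3.2 ± 0.77) and Hspa8 were higher among 11 acute stress genes (set test adjusted p = 0.655), and Atf3 (2.28 ± 0.45) among 10 AP-1 genes (set test adjusted p = 0.33). Receptor genes gave a higher Egfr (2.37 ± 0.76) and lower Fgfr2 (-6.31) and Fgf2 (-6.11). Of 7 endothelial markers Pecam1 and Cdh5 were higher, the latter at 222 ± 379 CPM, with an SD above the mean. The other 5 changed downward without passing, and the list did not move as a set (set test adjusted p = 0.998). The respiratory or stratified epithelium markers Krt13 (at least 59.9-fold) and Trp63 (at least 104-fold) were lower.

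The largest rises in Smarcb1 KO lines in vehicle were the cardiac factor Tbx20 (110 ± 17.4 CPM, 12.25 ± 2.25, adjusted p = 0.00254), Apba2 (at least 304-fold), the matrix gene Tnr, the Wnt inhibitor Wif1 (10.13 ± 1.17, adjusted p = 6.75e-05), Pcdh11x, Mamstr, Cbln1 and Ng23. The largest falls were Scarf2 (at least 1290-fold), Bmp5 (at least 975-fold), Hspb8 (at least 573-fold), Adamts12 (at least 570-fold), Cldn6 (-12.03), Gpr64 (-11.87), the hyaluronan synthase Has2 (at least 435-fold) and Serpinb1a (at least 344-fold). The count of calls was 1618 without BS53736, 1704 without BS53965 and 1738 without B47275. Of the genes called in Smarcb1 KO lines in vehicle, 1925 were also called in the same direction under CKI. For Arid1a KO this number was 69 and for Arid2 KO it was 4. Both comparisons used the same KO and Braf lines, so line differences not due to the knockout would recur in both.

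The knockouts were compared for shared genes in vehicle. Arid1a KO and Smarcb1 KO shared 230 lower genes where 46.4 were expected from the list sizes (Fisher's exact test adjusted p = 1.79e-110) and 42 higher genes where 10.6 were expected (exact adjusted p = 2.57e-14), while 12 genes were called in opposite directions. Arid2 KO shared 6 lower genes with Smarcb1 KO (0.785 expected, exact adjusted p = 5e-05) and 2 lower and 1 higher with Arid1a KO (exact adjusted p = 0.0324 and 0.0294). The correlation of the log2 changes across genes, which are not independent replicates, was 0.529 for Arid1a KO with Arid2 KO, 0.425 for Arid1a KO with Smarcb1 KO and 0.456 for Arid2 KO with Smarcb1 KO, against 0.497, 0.498 and 0.496 in simulated unchanged groups with the same controls. Their covariance was 1.488, 1.656 and 1.553 for the 3 pairs, of which the spread of the shared Braf lines would give a covariance of 0.663, leaving 0.825, 0.993 and 0.89. Part of the excess can thus come from the shared controls, which are too few to be halved.

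The inhibitor was compared with vehicle within each genotype to ask whether blocking RAF and MEK restores thyroid genes. The labels leave open whether vehicle libraries also received bovine TSH. Changes under CKI, in all genotypes, can therefore not be assigned to the inhibitor alone. In Braf lines no gene was called by edgeR without the block, with 1744 genes at an unadjusted p under 0.05, 315 called by DESeq2 and 388 called with the line as block (222 higher, 166 lower). Tg was higher under CKI in each line, from 7.42 to 270 CPM in B47275, from 1.65 to 7 in B48051 and from 1.55 to 255 in B52482, with a change of 5.65 ± 1.62 that did not pass (adjusted p = 0.231). Tshr (6.03 ± 2, adjusted p = 0.272) and Slc5a5 (-1.34 ± 0.73, adjusted p = 0.52) did not pass either. With the line as block Tg (5.01 ± 1.29, adjusted p = 0.0701) and Tshr (4.56 ± 1.54, adjusted p = 0.129) did not pass. With the block the endocytic receptor Lrp2 rose (6.61 ± 0.94, adjusted p = 0.0111), and 5 thyroid differentiation genes passed adjusted over the list alone and 0 over all genes (set test adjusted p = 0.0153, and adjusted p = 0.393 with an estimated correlation). MAPK output genes fell with the block for 4 of 19 members (11 adjusted over the list alone), namely Dusp4 (-2.48 ± 0.19, adjusted p = 0.000826), Etv5 (-1.89 ± 0.25, adjusted p = 0.00862), Etv1 and Spry4. The MAPK output set test without the block gave adjusted p = 2.18e-06, and adjusted p = 0.0411 with an estimated correlation. With the block these were 1.06e-07 and 0.0827, so the call was lost with an estimated correlation, as was every set test of CKI against vehicle in the blocked fit (0 of 92 passed). Glycolysis genes fell for 8 of 15 with the block, such as Ldha (-1.63 ± 0.2) and Slc2a1 (-1.54), and their blocked set test gave adjusted p = 6.62e-10, and adjusted p = 0.0827 with an estimated correlation (2.03e-08 and 0.0364 without the block). Cell cycle genes fell as a set (adjusted p = 1.29e-19, and adjusted p = 0.239 with an estimated correlation), with 14 of 28 lower adjusted over the list alone.

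Single mesenchymal and TGF-beta and YAP response genes rose in Braf lines under CKI in the blocked fit. Smooth muscle actin Acta2 (9.49 ± 1.07, adjusted p = 0.00634) and Sparc (1.62) rose among mesenchymal genes, and Tgfb2 (2.82), Amotl2 and Cyr61 rose among TGF-beta and YAP response genes. That list's blocked set test gave adjusted p = 0.000295, and adjusted p = 0.162 with an estimated correlation (0.000702 and 0.0411 without the block). The AP-1 genes Fosl2 (1.47) and Atf3 (1.88), the receptor Fgfr2 (3.62) and the matrix gene Dcn (5.57) rose. The largest rises by the naming rule applied to the blocked fit were Acta2, Ces1d (7.43), Galntl1, Igfbp2 (6.93), Nkain4, Lrp2, Npr3 and Fam189a2. The largest falls were Csn3 (-6.08), Pyhin1 (-5.89), Klhl4, Cd53, 2310002L13Rik, Fer1l6, Nxph3 and Kcnn4 (-4.01). Without B47275 the blocked count was 51, without B48051 it was 63 and without B52482 it was 6.

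**Figure D4:**
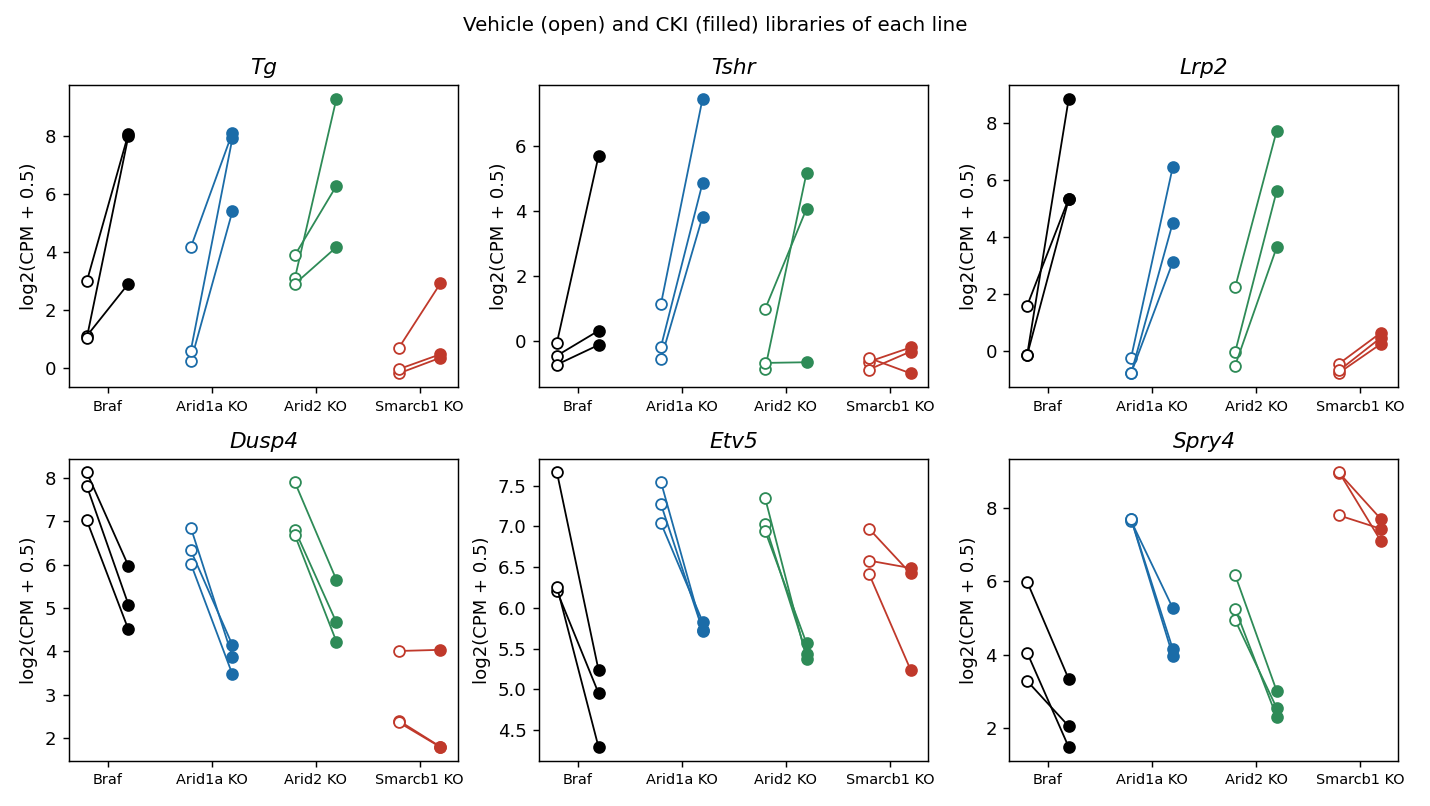
Log2(CPM + 0.5) of Tg, Tshr, Lrp2, Dusp4, Etv5 and Spry4 in each of the 12 lines, with open points for vehicle and filled points for CKI joined per line. Tg reaches 270, 7 and 255 CPM under CKI in the Braf lines and 0.779, 7.08 and 0.891 CPM in the Smarcb1 KO lines.

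In Arid1a KO lines thyroid genes were higher and MAPK output genes lower under CKI than in vehicle. In all, 2177 genes were called (1107 higher, 1070 lower), 3509 with only the 2 compared groups in the fit and 202 to 555 with a line left out. Of 12 thyroid differentiation genes 4 rose (5 adjusted over the list alone), namely Tg (187 ± 127 against 6.38 ± 9.58 CPM, 4.89 ± 1.56, adjusted p = 0.045), Tshr (72.4 ± 89 against 0.756 ± 0.827 CPM, adjusted p = 0.0375), Thra (1.88 ± 0.6) and Thrb (5.63 ± 1.4, adjusted p = 0.0146). The set test gave adjusted p = 0.0071, and adjusted p = 0.148 with an estimated correlation. With the line as block 7 of 12 rose, which added Nkx2-1 (1.99 ± 0.41, adjusted p = 0.00525), Glis3 and Dio2, and Tg changed by 5.81 ± 1.26 (adjusted p = 0.0068). Without the block, none of the 4 passed with any 1 of the Arid1a KO lines left out. With it Tg, Tshr, Thra, Thrb and Nkx2-1 passed with each line left out. Lrp2 rose (7.8 ± 1.64, adjusted p = 0.00647), and Kcnq1 and Slco4a1 fell. MAPK output genes fell for 9 of 19 members and rose for Epha4 and Ier3 (10 and 2 adjusted over the list alone), with Etv4 at 11.3 ± 9.33 against 166 ± 30.3 CPM (-3.86 ± 0.8, adjusted p = 0.00583), Spry4 (-3.1 ± 0.64, adjusted p = 0.00617), Ccnd1, Dusp4, Dusp6, Etv5, Fosl1, Spred2 and Spred3 lower. Its set test gave adjusted p = 4.46e-05, and adjusted p = 0.0559 with an estimated correlation. Cholesterol synthesis genes rose for 7 of 19 (12 adjusted over the list alone), such as Dhcr7 (2.01 ± 0.4, adjusted p = 0.00508) and Idi1 (2.03), with a set test adjusted p = 2.16e-06, and adjusted p = 0.429 with an estimated correlation. Cyr61 (2.98 ± 0.48), Thbs1 (3.31), Fosl2 (2.63 ± 0.3, adjusted p = 0.000459), Acta2 (10.62) and Fgfr2 (5.17) rose.

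Cell cycle genes fell for 4 of 28 in Arid1a KO lines, with Mcm2 (-1.48) and Mcm3 (-1.66) among them (set test adjusted p = 1.25e-08, and adjusted p = 0.566 with an estimated correlation), and glycolysis genes fell for 6 of 15, such as Pdk1 (-2.47) and Slc2a1 (-1.86) (adjusted p = 0.00394, and adjusted p = 0.254 with an estimated correlation). The ATPase Smarca2 rose (146 ± 4.53 against 35.6 ± 9.02 CPM, 2.04 ± 0.49), and Actl6a, Pbrm1 and Smarcc1 fell. Ifi44 (-5.4) and Bst2 (-3.22) fell in the group of Arid1a KO lines, of which BA45198 alone expressed interferon genes in vehicle. Without BA45198 these changes were 1.02 and 0.66 and did not pass. The largest rises were Fmod (13.08), Spna1 (12.04), Crygs (at least 408-fold), Dgkg (at least 401-fold) and Nkain4 (at least 322-fold), and the largest falls were Try5 (-12.38), Csn3 (at least 323-fold), Plvap, Chrna1 and Esm1. With the block 5053 genes were called, 2158 of them shared with the 2177. The count without the block was 555 without BA45198, 358 without BA47473 and 202 without BA49112, and the blocked count was 3296, 2828 and 2306.

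In Arid2 KO lines 22 genes were called under CKI (15 higher, 7 lower), 0 with only the 2 compared groups in the fit, 0 with any line left out and 981 with the block. The matrix gene Thbs1 (5130 ± 1280 against 125 ± 61.3 CPM, 5.36 ± 0.99) and Fosl2 (1.62 ± 0.29) rose, both at adjusted p = 0.0423, with Cacna1g (6.88), D0H4S114, Dkk3 (5.82, adjusted p = 0.0209) and Serpinb6b. Fer1l6 (-6.09, adjusted p = 0.0109), Slc30a4, Slc25a39, Rplp2 and Fau fell. Tg (240 ± 335 against 9.75 ± 3.95 CPM, 4.62 ± 1.54, adjusted p = 0.194), Tshr (5 ± 1.88) and Lrp2 (5.81 ± 1.43, adjusted p = 0.089) did not pass without the block. With it Lrp2 passed (6.01, adjusted p = 0.00673), and Tg (3.18 ± 1.17, adjusted p = 0.123) and Tshr (4.7 ± 1.34, adjusted p = 0.063) did not. MAPK output genes were lower as a set (adjusted p = 1.51e-08, and 0.0147 with an estimated correlation, which became 0.0827 with the block) with 10 of 19 lower adjusted over the list alone and 0 over all genes. With the block 7 of 19 fell, among them Dusp4 (-2.29 ± 0.19, adjusted p = 0.000843), Ccnd1 (-3.41) and Spry4 (-2.94). The TGF-beta and YAP response list was higher as a set (adjusted p = 8.91e-06, and 0.0147 with an estimated correlation, which became 0.112 with the block). Glycolysis genes were lower as a set (adjusted p = 2.6e-06, and adjusted p = 0.0559 with an estimated correlation). Muscle genes such as Acta1 (2.91) and Tnnt3 (2.87) rose with the block, and line AB52980 held most of their counts. No call was left without AB51189, AB52980 or AB55694. The blocked count was 156, 364 and 152 without each of these lines.

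In Smarcb1 KO lines 5 genes were called under CKI (4 higher, 1 lower), 0 with only the 2 compared groups in the fit and 165 with the block, at the low depth of libraries BS53958 and BS53965. The chaperone gene Cryab rose (3.56 ± 0.59) and the kinase gene Cdk20 fell (-3 ± 0.5), both at adjusted p = 0.0377. Tg was at 2.92 ± 3.61 against 0.656 ± 0.4 CPM (2.22 ± 1.54, adjusted p = 0.767), and Tshr (0.81 ± 2.18) and Lrp2 (2.45 ± 1.6, adjusted p = 0.745) did not pass, and with the block Tg (1.86, adjusted p = 0.565) and Lrp2 (2.47, adjusted p = 0.366) did not pass. MAPK output genes were lower as a set (adjusted p = 1.62e-05, and adjusted p = 0.0411 with an estimated correlation, which became 0.112 with the block), with 2 of 19 lower adjusted over the list alone and 0 over all genes. Cholesterol synthesis genes fell for 5 of 19 with the block (12 adjusted over the list alone), such as Sc4mol (-2.01 ± 0.29, adjusted p = 0.0176), Sqle and Fdft1, with a blocked set test adjusted p = 4.04e-14, and adjusted p = 0.167 with an estimated correlation. Interferon response genes were higher as a set (adjusted p = 8.91e-06, and adjusted p = 0.566 with an estimated correlation). Pdk1 (-1.4) fell and Fgfr2 (5.45) rose with the block. The largest blocked rises were Fgfr2, Cacna1g, Ogn, Ccdc80 and 3110082D06Rik, and the largest falls were Atp13a4 (-6.49), Gm17322, Fer1l6, Cd53 and Padi2. The count was 41 without BS53736, 15 without BS53958 and 0 without BS53965, and the blocked count was 107, 318 and 0.

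The difference between the CKI responses of KO and Braf lines was tested directly, since the title speaks of resistance to redifferentiation. No gene was called by edgeR without the block in any of the 4 tests. At an unadjusted p under 0.05 there were 801 genes for Arid1a KO, 124 for Arid2 KO, 659 for Smarcb1 KO and 184 for their mean, and DESeq2 called 37, 7, 44 and 7. With no difference a share of 0.05 of the 15634 genes is expected, so 801 is near that share and the others lie below it. With the block these unadjusted counts were 1945, 402, 1419 and 634. Without the block the pairing of libraries is ignored, so differences in response can be missed. The response of Tg differed by -0.76 ± 1.9 in Arid1a KO, -1.03 ± 1.89 in Arid2 KO, -3.43 ± 2.08 in Smarcb1 KO and -1.74 ± 1.59 in the mean of the 3 KO. With the block these differences were 0.8 ± 1.65, with the sign changed, -1.83 ± 1.67, -3.15 ± 1.89 and -1.39 ± 1.39. For Smarcb1 KO, Tshr (-5.22 ± 2.94, and -4.02 ± 2.52 with the block) and Lrp2 (-4.88 ± 2.18, and -4.14 ± 1.78 with the block) did not pass, so a weaker thyroid response of Smarcb1 KO lines was not shown. In the blocked fit Dusp4 fell less in Smarcb1 KO than in Braf lines (2.09 ± 0.27, adjusted p = 0.0416), from a much lower level in vehicle. It was at 8.34 ± 6.26 CPM in vehicle and 7.28 ± 7.45 CPM under CKI in Smarcb1 KO lines. In Braf lines it was at 210 ± 75.5 and 39.2 ± 20.6 CPM. Adamts2 (-7.16 ± 0.79, adjusted p = 0.0176), Dlc1, Ncam1 and Zzef1 differed the other way, with a lower response in Smarcb1 KO lines. Of the 23 genes called for Arid1a KO with the block, 18 were higher and 5 lower, such as the lipase gene Lpl (6.99 ± 0.87, adjusted p = 0.0216), Kng2 (8.68 ± 1.2, adjusted p = 0.0321) and Dcn (-5.9 ± 0.84). Dcn was already higher in Arid1a KO than in Braf lines in vehicle, at 468 ± 478 against 3.45 ± 3.42 CPM. The blocked fit called 0 genes for Arid2 KO and 0 for the mean.

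The response of cholesterol synthesis genes to CKI differed by genotype in the set tests. A higher response here means a more positive log2 change under CKI than in Braf lines, and a lower response a more negative one. In Arid1a KO lines the response of the list was higher than in Braf lines (14 of 19 members adjusted over the list alone and 0 over all genes; set test adjusted p = 5.49e-23, and adjusted p = 0.372 with an estimated correlation). It started from a lower level, with a median log2 difference from Braf lines of -1.42 in vehicle and 9 of 19 members lower. Under CKI that difference was 0.19, with 0 of 19 members called (set test adjusted p = 0.25). The median change of the list per line was 1, 1.07 and 1.11 in Arid1a KO, -0.58, -0.54 and 0.05 in Braf and -0.36, -0.72 and -1.13 in Smarcb1 KO lines, and in Smarcb1 KO it was lower than in Braf (adjusted p = 0.00377, and adjusted p = 0.674 with an estimated correlation). Arid2 KO lines (1.52e-09, and adjusted p = 0.641 with an estimated correlation) and the mean of the 3 KO (1.5e-09, and adjusted p = 0.641 with an estimated correlation) had a higher response. Cell cycle genes, which fell as a set in Braf lines, had a more positive change in Arid2 KO and Smarcb1 KO lines. For Arid2 KO the set test gave adjusted p = 5.04e-09, and adjusted p = 0.641 with an estimated correlation. For Smarcb1 KO it gave adjusted p = 0.000117, and adjusted p = 0.674 with an estimated correlation. The lower interferon response in Arid1a KO lines (1.66e-06, and adjusted p = 0.641 with an estimated correlation) came with line BA45198. The blocked count for Arid1a KO was 0 without B47275, B48051 or BA47473, 12 without BA45198, 10 without BA49112 and 194 without B52482. For Smarcb1 KO it was 1 without B47275 or B48051, 0 without B52482 or BS53965, 20 without BS53736 and 19 without BS53958, and without the block it was 23 without BS53736.

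Under CKI, KO lines were set against Braf lines to compare the levels reached. Smarcb1 KO lines had lower thyroid genes, with 5 of 12 differentiation genes lower. Tg was at 2.92 ± 3.61 against 177 ± 148 CPM (-5.86 ± 1.66, adjusted p = 0.0194), Tshr at 0.222 ± 0.196 against 17.5 ± 29.2 CPM (-6.27 ± 2.13, adjusted p = 0.0413) and Glis3 at 7.04 ± 6.09 against 174 ± 59.1 CPM (-4.59 ± 0.89, adjusted p = 0.00247), and Dio2 and Duox1 were lower. Adjusted over the list alone 5 were lower and 1 higher, and the set test gave adjusted p = 0.108. Hormone handling genes were lower for 6 of 12 (10 adjusted over the list alone; set test adjusted p = 0.00073, and adjusted p = 0.0596 with an estimated correlation), with Lrp2 at 0.886 ± 0.187 against 182 ± 245 CPM (-7.71 ± 1.6, adjusted p = 0.00379), and Ano1, Clcn5, Hhex, Kcnq1 and Sorbs2 lower. Of the 11 lower thyroid genes, Glis3, Lrp2 and Clcn5 passed with each line left out. The call of Tg, Smarcb1 KO vs Braf, CKI was lost without BS53736 (adjusted p = 0.0608), without BS53965 (adjusted p = 0.065) and with only the 2 compared groups in the fit (adjusted p = 0.0939). Braf line B48051 was at 7 CPM of Tg, as low as Smarcb1 KO line BS53958 at 7.08. Without lines BS53958 and BS53965, whose CKI libraries were shallow, 1 of the 24 thyroid genes was called lower with 1 Smarcb1 KO line left. The change of Tg, Smarcb1 KO vs Braf, CKI was then -7.85 (adjusted p = 0.169) and that of Lrp2, Smarcb1 KO vs Braf, CKI was -8.04 (adjusted p = 0.131), so these calls ended without a smaller change. MAPK output genes were higher for 6 of 19 and lower for 4, with Spry4 at 171 ± 35.2 against 5.17 ± 3.87 CPM (5.03 ± 0.71, adjusted p = 0.000266), Etv5, Fosl1 and Myc higher and Dusp4, Epha4, Ier3 and Phlda1 lower. Cell cycle genes were higher for 16 of 28 (24 adjusted over the list alone), such as Pcna (1.51) and E2f1 (1.33), with a set test adjusted p = 2.35e-09, and adjusted p = 0.822 with an estimated correlation.

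TGF-beta and YAP response genes were lower in Smarcb1 KO lines under CKI for 8 of 16 (set test adjusted p = 0.000337, and adjusted p = 0.0596 with an estimated correlation), with Ctgf at a change of -7.09, and cholesterol genes for 10 of 19 (adjusted p = 1.96e-05, and adjusted p = 0.822 with an estimated correlation), such as Fdft1 (-2.38). Fn1 (104 ± 97.5 against 7050 ± 1200 CPM), Acta2 (-10.62) and Col1a1 (-10.86) were lower, and Hk2 (-3.98) too. MHC class I genes were higher for 3 of 12 (adjusted p = 0.0261, and adjusted p = 0.822 with an estimated correlation). Of 3618 genes called, 1572 were higher and 2046 lower. The largest rises were Tbx20 (at least 3000-fold), Crabp1 (12.25), Apba2, Ugt1a7c and Dner, and the largest falls were Kcnj16 (at least 3320-fold), Gpr64 (at least 1110-fold), Adamts12 (at least 992-fold), Bmp5 (at least 790-fold) and Slpi (at least 401-fold). The count was 2242 without B47275, 2214 without BS53958, 939 without BS53958 and BS53965 and 521 with only the 2 compared groups in the fit.

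Arid1a KO and Arid2 KO lines reached Tg levels under CKI that did not differ detectably from Braf lines, with changes of 0.08 ± 1.32 and 0.43 ± 1.32. In Arid1a KO lines the hormone handling list was lower as a set (set test adjusted p = 0.0489, and adjusted p = 0.569 with an estimated correlation). Of its 12 members 3 were lower adjusted over the list alone and 0 over all genes. For Arid1a KO 115 genes were called (38 higher, 77 lower), with Cdh2 (-1.77 ± 0.4, adjusted p = 0.0452) and Ankrd1 (-1.94 ± 0.43) lower and Dpt (8.24) higher. The largest rises were Kng2 (12.04), Ptgfr (at least 252-fold), Slit3 (9.54 ± 1.42, adjusted p = 0.0113), Dlk1 and Lpl, and the largest falls were the claudin gene Cldn6 (at least 4430-fold), Kcnj16, Wnt7b, Slc38a1 and 4930506M07Rik. Fibroblast genes were higher as a set (adjusted p = 2.42e-06, and adjusted p = 0.0732 with an estimated correlation). Mesenchymal genes other than Cdh2 mostly went up, with 15 of 20 changes positive (set test adjusted p = 5e-04, and adjusted p = 0.822 with an estimated correlation). Epithelial genes were lower as a set in Arid1a KO (adjusted p = 2.03e-11, and adjusted p = 0.733 with an estimated correlation) and Arid2 KO lines (adjusted p = 5.8e-11, and adjusted p = 0.733 with an estimated correlation), with 18 and 14 members lower adjusted over the list alone, and 0 over all genes. Braf line B52482 was at a median of -0.27 under CKI, Arid1a KO lines at -0.71, -0.6 and -0.67 and Arid2 KO lines at -0.18, -0.05 and -0.62. The count for Arid1a KO was 5 with only the 2 compared groups in the fit, 37 without B47275, 15 without B48051, 488 without B52482, 31 without BA45198, 16 without BA47473 and 2 without BA49112. For Arid2 KO 10 genes were called (3 higher, 7 lower), with the kinase gene Csk higher (0.76 ± 0.14, adjusted p = 0.049) and Pon3 (-4.1 ± 0.68, adjusted p = 0.039) and Tapbpl (-1.26 ± 0.19, adjusted p = 0.0333) lower as in vehicle. Skeletal muscle genes were higher for 5 of 5 adjusted over the list alone, from line AB52980. The count for Arid2 KO was 0 with only the 2 compared groups in the fit, 0 without B47275, AB51189 or AB52980, 1 without B48051, 2 without AB55694 and 38 without B52482.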

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

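The tests of explanations and the splits of samples in this part were chosen after the results were seen, except the refit without the most abundant wildtype genes. The tests of the response difference with edgeR, with DESeq2 and with the line as block were planned. Fits with thinned counts, without both shallow lines, or with the block and a line left out were added later.

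The responses to CKI in Arid1a KO and in Braf lines differed for 23 genes by a test of the difference itself, with the line as block. By the naming rule these were Kng2 (8.68), Lpl (6.99), Fst (5.22), Smpd3 (5.14), Plekha7 (4.29), Fgf7 (3.82), Tmem56 (3.37) and Tmod2 (2.81), with a higher response in Arid1a KO lines, and Zc3hav1 (-1.17), Synj2 (-2.28), Xylt1 (-2.68), C630004H02Rik (-3.29) and Dcn (-5.9), with a lower one, all as log2 differences. The same test for Smarcb1 KO called 5 genes, namely Dusp4 (2.09), Zzef1 (-1.68), Ncam1 (-3.37), Dlc1 (-3.5) and Adamts2 (-7.16). Dusp4 was already low in Smarcb1 KO lines in vehicle, at 8.34 ± 6.26 CPM against 210 ± 75.5 CPM in Braf lines. Dcn was already high in Arid1a KO lines in vehicle, at 468 ± 478 CPM against 3.45 ± 3.42 CPM in Braf lines. Without the block 0 genes passed in edgeR for both knockouts, with 801 and 659 genes at an unadjusted p under 0.05, and DESeq2 called 37 and 44. Of the 15634 genes tested, a share of 0.05 is expected at this threshold with no difference, which is near 801 and above 659. None of the named genes passed in all blocked fits with 1 line left out. The 10 splits of the lines are too few for a share under 0.05, and the highest other count was 0 for Arid1a KO and 1 for Smarcb1 KO with the block. For Arid2 KO the blocked count was 0 in the real split and 1 in another, so 10 of 10 splits gave as many genes. Without the block all 10 splits gave 0 for each knockout, and for the mean of the 3 KO all 100 drawn splits gave as many genes as the real 0. Any split reaches a real count of 0, so in these cases the share was fixed in advance and tests nothing.

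For the comparisons of KO with Braf, the 10 splits of 6 libraries are too few for a share under 0.05. In vehicle the real counts of 567, 8 and 2837 stood against highest other counts of 1, 0 and 0, and under CKI those of 115, 10 and 3618 against 0, 0 and 1. In each case the real split was the 1 split with as many genes. For Braf vehicle against wildtype the real count was 7815 and the highest other 0. For CKI against vehicle without the block, 10, 1, 2 and 5 of 10 splits gave as many genes in Braf, Arid1a KO, Arid2 KO and Smarcb1 KO, with highest other counts of 218, 1, 103 and 496 against real counts of 0, 2177, 22 and 5. For Braf the share was fixed in advance by the real count of 0. The splits with 218, 103 and 496 genes set lines apart and so point to a structure of the samples by line, and splits that part all 3 pairs gave 0 other than the real one. With the block 4 splits part the pairs, and the highest other counts were 0, 0, 0 and 1.

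Epithelial genes were lower in KO than in Braf lines in vehicle as a set at the preset correlation, but not with an estimated correlation (adjusted p = 0.699, 0.576 and 0.699 for Arid1a KO, Arid2 KO and Smarcb1 KO). Of the 3 Braf vehicle libraries 2 lay above all 9 KO libraries while B52482 lay among them. Thyroid tissue in the libraries with epithelial genes was argued against, since Tg and Iyd reached at most 0.238% of the level that such a share of tissue would bring. A wrong label of B52482 as an Arid1a KO or Smarcb1 KO line was argued against, since its Arid1a level was at least 1.42 times the highest in Arid1a KO libraries, and an Arid2 KO line could not be excluded from the counts. Loss of a subunit stays open as a cause, and it may not be the whole cause, since 1 Braf line had low levels of these genes too.

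Thyroid genes were lower in Smarcb1 KO than in Braf lines under CKI for 11 of 24 members of the thyroid lists. Depth as the whole cause was argued against, since 10 members were lower with every library thinned to the same depth. Without the shallow lines 1 member was called lower with 1 line left, while the change of Tg, Smarcb1 KO vs Braf, CKI was -7.85 against -5.86 with all lines. Glis3, Lrp2 and Clcn5 passed with each line left out and Tg did not, with Braf line B48051 at 7 and Smarcb1 KO line BS53958 at 7.08 CPM of Tg. MAPK output genes fell in each Smarcb1 KO line, and at most 0.04% of random lists had a median change as low. Their median log2 change was -1.04 in BS53736, -0.29 in BS53958 and -0.58 in BS53965. In Braf lines it was -0.46, -0.67 and -1.09. Random lists hold unrelated genes and do not measure how a jointly regulated list varies between libraries. CKI libraries without inhibitor, or with weaker inhibition, were therefore not excluded. A weaker response of Smarcb1 KO lines stays open, because the difference in response did not pass for any thyroid gene, and differences between lines that are not due to Smarcb1 were not tested.

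Markers of other cell types were present in libraries marked wildtype, with 6 of 9 marker lists higher in all 3 of these libraries than in all 24 tumor line libraries. The exceptions were fibroblast, skeletal muscle and respiratory markers. This is consistent with tissue that holds its other cell types, while the source name speaks of a tumor cell line. After the 10 most abundant wildtype genes, with 31.2% of the counts, were left out, 56 of 65 markers were lower in Braf lines, and 55 of 64 before. This refit could not test a cause of the higher markers. Abundant genes would lower the share of all other genes in wildtype libraries, and TMM scaling already trims extreme genes.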

How the results depend on the processing

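Tests without lines BS53958 and BS53965, with thinned counts, and of the blocked fit with changed inputs were chosen after seeing the data, and the other alternatives were planned. With RLE size factors 1170 of 1177 values of named genes kept their direction and side of the threshold, and the count for Arid2 KO against Braf under CKI was 6. DESeq2 called 1573 and 602 genes for Arid1a KO and Arid2 KO in vehicle, 315, 3411, 574 and 301 under CKI in Braf, Arid1a KO, Arid2 KO and Smarcb1 KO, 37, 7, 44 and 7 for the differences in response of Arid1a KO, Arid2 KO, Smarcb1 KO and their mean, and 971 and 438 for Arid1a KO and Arid2 KO against Braf under CKI. With no filter, where more genes were tested, Arid1a KO and Arid2 KO in vehicle gave 365 and 3, CKI in Arid2 KO and Smarcb1 KO gave 6 and 0, and Arid1a KO and Arid2 KO under CKI gave 73 and 1. The stricter filter gave 20 for Arid2 KO in vehicle and 41 for CKI in Arid2 KO. With only the compared groups, and so fewer libraries for the spread, vehicle counts were 24, 0 and 785, CKI counts were 3509, 0 and 0 in Arid1a KO, Arid2 KO and Smarcb1 KO, and counts against Braf under CKI were 5, 0 and 521. With all 27 libraries, Arid1a KO and Arid2 KO gave 936 and 35 in vehicle and 320 and 18 under CKI, and CKI in Arid2 KO and Smarcb1 KO gave 87 and 18. With the line as block, CKI counts were 388, 5053, 981 and 165 in Braf, Arid1a KO, Arid2 KO and Smarcb1 KO, and the response of Arid1a KO and Smarcb1 KO gave 23 and 5. The block changed no other count. Without lines BS53958 and BS53965 each Smarcb1 KO group held 1 library, assumed to vary like the other groups, and Smarcb1 KO gave 837 in vehicle, 939 against Braf under CKI, 1 for the response and 9 for CKI with the block. With thinned counts, Arid1a KO and Arid2 KO in vehicle gave 341 and 0, CKI in Smarcb1 KO 0, Arid1a KO and Arid2 KO under CKI 60 and 0, and the blocked Smarcb1 KO response 3. At least 2-fold changes left overlaps of 1 lower gene for Arid1a KO with Arid2 KO and 27 higher genes for Arid1a KO with Smarcb1 KO. Beyond the numbers of genes and libraries, the cause was not tested.

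With each line or library left out, counts ranged from 69 to 1153, 0 to 147 and 1618 to 2318 for Arid1a KO, Arid2 KO and Smarcb1 KO in vehicle, and from 2 to 488, 0 to 38 and 2214 to 3131 under CKI. The CKI counts ranged from 202 to 555 in Arid1a KO and 0 to 41 in Smarcb1 KO, and were 0 in Braf and Arid2 KO. The response counts ranged from 0 to 23 in Smarcb1 KO and were 0 in the others. Braf vehicle against wildtype ranged from 6339 to 6994. With the line as block the ranges were 6 to 63, 2306 to 3296, 152 to 364 and 0 to 318 for CKI, 0 to 194 and 0 to 20 for the response of Arid1a KO and Smarcb1 KO, 0 for Arid2 KO and 0 to 1 for the mean. Directions reversed for Ifi44 (1.02, range -6.08 to 1.02 over the lines left out) and Bst2 (0.66, range -3.84 to 0.66) under CKI in Arid1a KO without BA45198, for Spock1, Smarcb1 KO vs Braf, vehicle, without BS53958 (-0.42, range -0.42 to 11.36), and for Acta1 (-0.03) under CKI in Arid1a KO with the block and thinned counts. The first 3 of these rested on the line left out. Of 92 set tests that passed, 14 did so with an estimated correlation, and 0 of the 31 that passed for CKI against vehicle with the block did. Of 125 named genes called between Braf and wildtype, 111 passed without every library in turn, against 4 of 35, 0 of 6 and 38 of 80 for Arid1a KO, Arid2 KO and Smarcb1 KO in vehicle and 0 of 14, 0 of 3 and 40 of 84 under CKI. For CKI against vehicle 6 of 75, 0 of 12 and 0 of 2 passed in Arid1a KO, Arid2 KO and Smarcb1 KO. With the block 2 of 38, 62 of 109, 23 of 53 and 0 of 17 passed in Braf, Arid1a KO, Arid2 KO and Smarcb1 KO, and 0 of 13 and 0 of 5 for the response of Arid1a KO and Smarcb1 KO. The shallowest library, of Smarcb1 KO under CKI, held 2884130 counts, which limits what can be detected in that group.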

Other observations

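All values here were looked up after the data were seen. Arid2 KO line AB52980 expressed skeletal muscle genes, with Acta1 at 94.1 CPM in vehicle and 917 CPM under CKI, Tnnt3 at 28.9 and 299 CPM, and Mylpf at 59.6 and 337 CPM. Interferon response genes were expressed in Arid1a KO line BA45198 in vehicle, with Isg15 at 157 CPM, Ifit1 at 138, Bst2 at 161 and Ifi44 at 115 CPM. Pth was at 1950, 1040 and 36.9 CPM in the libraries marked wildtype. Among sex-linked genes, Xist was at 684 CPM or more in both libraries of lines B47275, AB51189 and BS53965 and in 1 wildtype library. The Y-linked genes Ddx3y and Eif2s3y were read in both libraries of the other lines, so the paired libraries of all 12 lines matched in sex. A swap between lines of the same sex, such as the Arid1a KO lines, would not show in this check. Arid1a KO lines all read Y-linked genes and Braf line B47275 read Xist, so these genotypes differed in sex makeup. Kdm5d was at 0 CPM in both libraries of line BS53736. The median absolute log2 change under CKI per line was 0.281, 0.277 and 0.395 in Braf, 0.453, 0.458 and 0.556 in Arid1a KO, 0.508, 0.304 and 0.286 in Arid2 KO and 0.326, 0.208 and 0.337 in Smarcb1 KO lines.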
